A study of Bacillus subtilis with 4 samples.

How the data were processed

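Total RNA of *Bacillus subtilis* 168 wild type and of a cshA mutant of that strain was compared on 4 DNA arrays of 2 channels each. Per the labels, cultures in CSE-Glu medium were sampled in mid exponential phase (OD600 near 0.8) and in early stationary phase (OD600 from 2.2 to 2.4), with no treatment. Per the labels' growth protocol, each phase had 4 biological replicates, and the labelled cDNA of 2 of them was pooled for each slide, which gave 2 slides per phase. The labels' extraction protocol gives another number of replicate cultures, and the sources used here do not settle which is right. RNA was purified with a column kit and treated with DNase, and cDNA primed with random nonamers was coupled to Cy3 or Cy5, per the labels' protocols. On replicate 1 of each phase the mutant was labelled with Cy5 and on replicate 2 with Cy3. Replicate numbers follow accession order and pair no slides. Each slide holds a single phase, so phase and slide cannot be told apart in a comparison between phases.

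The deposited slide tables give spot intensities for each channel, per the file headers: a raw intensity, a local background, a net intensity, a second background and a net intensity after it. In the values, the net intensity equals raw minus background with negative results set to 0, and the last column equals the net intensity minus a background shared by a grid of spots, within the rounding of the tables. The scanner and the image software are not given in the sources used here. Spots that the authors left out (166 and 385 on exponential replicates 1 and 2, 399 and 400 on stationary replicates 1 and 2, of 8334 spots per slide) carry a marker in these columns and were left out. The authors' processed table in the series matrix holds a log ratio per gene and slide, on what its values show to be a natural log scale. Among the brightest genes, from the 0.75 quantile of intensity up, these deposited values correlated with the log2 ratios recomputed from the net intensities with r between 0.997 and 0.999 across genes and with slopes from 0.685 to 0.689, against a natural log of 2 of 0.693. Over all genes the slopes were 0.553 to 0.695. The direction is mutant over wild type on all 4 slides, and the column medians are 0.0137, -0.0156, 0.0281 and -0.00808. The normalization behind the authors' table is not given in the sources used here, so the table served as an alternative only. It holds values for 1739 and 3978 genes on exponential replicates 1 and 2 and for 4045 and 4043 genes on stationary replicates 1 and 2.

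Raw and background intensities were corrected with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50, over the spots not left out. Log2 ratios were normalized within each slide by a global loess curve with a span of 0.3 and 4 iterations, in which spots without a locus tag had a weight of 0. Ratios were turned to mutant over wild type, and the 2 spots of each ID were averaged. No normalization between slides was applied to the ratios. For comparisons between phases, the channel intensities after loess were brought to a common scale with Aquantile normalization. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. The slides carry 4106 locus tags. Of these, 4038 were given a symbol through a RefSeq gene table of assembly ASM904v1, used only for names and for which genes neighbour each other, and the others keep their locus tag. A further 61 IDs without a locus tag entered no comparison.

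A gene was taken as well above background on a slide and channel where its mean raw minus background intensity exceeded 2 median absolute deviations of that slide's local background, a limit chosen after the values had been seen. A gene not well above background on either slide of a group is given only as a bound. The bound sets the brighter group's mean log2 intensity after loess and Aquantile against, on each slide, the higher of the lowest signal among genes well above background and the gene's own signal. Each group holds 1 slide of each dye.

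The effect of the mutation was tested with limma on all 4 slides in a single fit with a coefficient for each phase, moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each phase holds 1 slide of each dye orientation, so a dye effect that is the same on both slides cancels in the mean. The difference between phases was a contrast of the same fit. Stationary over exponential phase was tested in each strain on the log2 intensities of its channel, 2 slides against 2. Genes without residual degrees of freedom in a fit were left out of it. Standard errors (SE) come from these fits, and n is the number of slides. In the mutant comparison the spread behind an SE is pooled over all 4 slides and moderated with a prior of 7.43 degrees of freedom. Such an SE is not the spread of the 2 slides of its phase. Genes at least 2-fold changed in the same direction on both slides of a phase were counted without a test. Correlations between slides are across genes, which are not independent replicates, so no p-value is given for them.

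Before the data were examined, the comparisons, their tests, most alternatives, the rule for named genes and 34 gene lists were fixed. Of 1172 list entries, 1079 matched a gene on the slides. Lists were tested with limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists, on genes with a ratio on all 4 slides. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted with adjustment over all genes and adjusted over the list alone. The rule names, for each phase of the mutant comparison, the 10 genes with the highest and the 10 with the lowest log2 ratio among those past the threshold with the same sign on both slides. It names the 5 highest and 5 lowest for the difference between phases, completed there with genes short of the threshold whose slides of a phase both lay at least 2-fold beyond both slides of the other, and the 5 highest and 5 lowest for each comparison between phases. It also names the 4 members with the smallest p of every list past its threshold, cshA itself, the other DEAD-box helicases and the RNA degradation genes. Other genes are said to be chosen after their values were seen.

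The fits were tested on simulated slides with known changes, built on the real backgrounds, left-out spots and mean levels with a set spread between slides. Every simulated spot lay above its local background, the spread was the same for all slides, and no gene-specific dye effect was added. On exponential replicate 1, 60.9% of the real Cy5 spots lay at or below background. The rates given next therefore need not hold for the real slides. In the exponential comparison 2%, 6%, 28% and 54% of genes simulated with 1.5-, 2-, 4- and 8-fold changes were called, with 0 false calls among 45 by limma, and in the stationary comparison 0%, 10.4%, 56.2% and 94%, with 0 false among 81. For the difference between phases, 1.06%, 1.04%, 20% and 55.2% were called. In the comparison of phases, 1.84% of the wild-type calls and 1.03% of the mutant calls were false. A simulated list of 40 genes shifted by 0.5 on the log2 scale was called by camera with the preset correlation (adjusted p = 7.42e-07) and not with an estimated correlation (adjusted p = 0.786), and 0 of 34 other lists were called. Simulated genes varied independently, whereas operons put several members of the real lists under a shared promoter. The simulation therefore cannot show how often camera with the preset correlation calls such lists wrongly. Most simulated genes changed 2-fold or less were not called. Whether the p-values measure culture-to-culture spread depends on the pools holding separate cultures, as the growth protocol states.

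Alternatives changed the background correction, the normalization within and between slides, a filter on genes below the 0.25 quantile of intensity, a dye term, the slides entering the fit, the treatment of replicate spots, the prior variance, the source of the values and each slide in turn. Those added after the data had been seen are a fit on genes well above background, counts of list members without exponential replicate 1, a motility list without the genes that follow comFC, and list medians of the difference between phases under other settings.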

Results

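The transcriptomes of *Bacillus subtilis* 168 and of its cshA mutant were compared in mid exponential and early stationary phase to ask which transcripts depend on CshA, a DEAD-box RNA helicase, in each phase. Every slide set mutant against wild-type cDNA of the same phase, with 2 slides per phase, swapped dyes and, per the labels' growth protocol, pools of 2 cultures per slide and strain. Ratios were obtained for 4082 and 4068 genes on exponential replicates 1 and 2 and for 4046 and 4057 genes on stationary replicates 1 and 2. Signal over background differed between the slides. On exponential replicate 1, the Cy5 channel, which holds the mutant, had a median raw intensity of 1083 over a median background of 1339. There 60.9% of spots lay at or below background, and 876 genes were well above background. On the other slides, 3203, 3528 and 3546 genes were well above background in Cy5. In Cy3, 3369, 3681, 3705 and 3479 genes were well above background on exponential replicates 1 and 2 and stationary replicates 1 and 2. Duplicate spots of a slide correlated with r of 0.834, 0.838, 0.830 and 0.788 in the same order.

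The transcript of cshA itself was lower in the mutant on all 4 slides. The log2 ratio of mutant over wild type was -2.31 and -3.88 on the exponential slides (mean -3.09, SE 0.42, n = 2, 8.53-fold, limma adjusted p = 0.00809) and -4.52 and -3.24 on the stationary slides (mean -3.88, SE 0.42, n = 2, 14.7-fold, limma adjusted p = 0.00295). In exponential phase its mutant signal was well above background on 1 of 2 slides. How the gene was disrupted is not given in the sources used here, so the residual signal was not assigned to a part of the gene. The genes around cshA did not pass the test: murF had log2 ratios of 0.79 and 0.54 in exponential and stationary phase, ydbS 0.41 and 0.10, and ydbT 0.17 and 0.15.

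Across genes, the ratios of the exponential slides correlated with a Pearson r of 0.262 and a Spearman rho of 0.147, and those of the stationary slides with 0.397 and 0.118. Over the 876 genes well above background in both channels of both exponential slides, r was 0.742 and rho 0.601. Over the 3183 such genes of the stationary slides, r was 0.533 and rho 0.257.

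**Figure D1:**
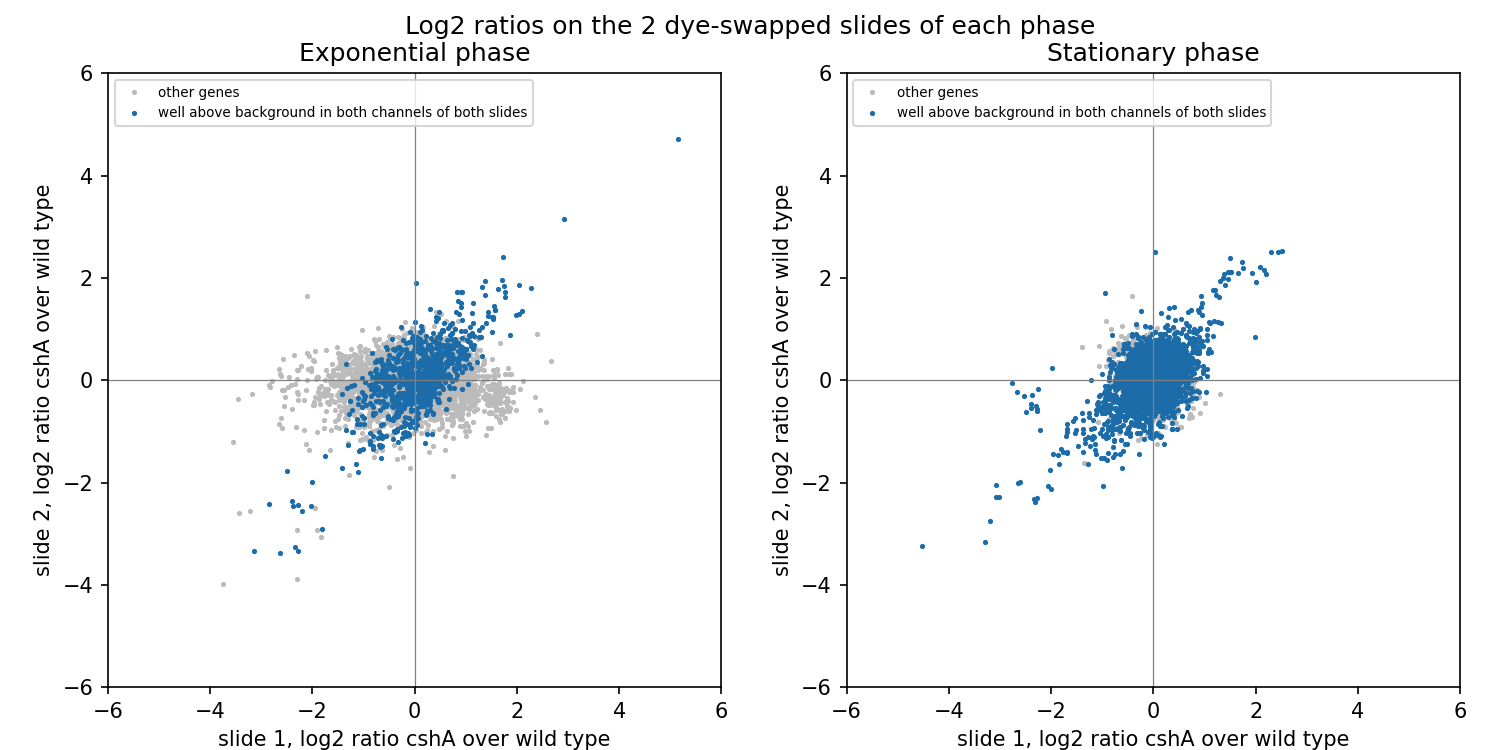
Log2 ratio of cshA mutant over wild type for each gene on replicate 1 (x axis) and replicate 2 (y axis) of exponential phase (left) and stationary phase (right), with genes well above background in both channels of both slides in blue and other genes in grey. Over the blue genes the Pearson r was 0.742 for 876 genes in exponential phase and 0.533 for 3183 genes in stationary phase.

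In exponential phase the transcript of pftA, which encodes a subunit of a pyruvate transporter, was 30.6-fold higher in the mutant (log2 4.93, SE 0.32, n = 2, limma adjusted p = 0.000203), and that of ytnP, which encodes a lactonase, 8.24-fold higher (log2 3.04, SE 0.27, n = 2, adjusted p = 0.00126). The respiratory nitrate reductase genes narG, narH and narJ rose by log2 2.04, 1.96 and 1.73. So did comEA, the DNA receptor of the competence machinery (log2 1.84, SE 0.28), the extracytoplasmic function sigma factor gene sigW (1.80, SE 0.28) and its anti-sigma factor gene rsiW (1.71, SE 0.28). The largest decrease was that of frlB, of the fructosamine degradation operon, at 14.5-fold (log2 -3.86, SE 0.27, n = 2, limma adjusted p = 0.000203). The arginine synthesis genes argJ (log2 -3.23, SE 0.43), argB (-3.00), argD (-2.80) and argC (-2.63) and carA of carbamoyl phosphate synthesis (-2.81) fell together, as did the flavodoxin genes fldN (-3.01, SE 0.32) and fldP (-2.89, SE 0.32).

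Of 4100 genes tested, 21 rose and 25 fell in exponential phase (limma, Benjamini-Hochberg), and 570 had an unadjusted p under 0.05. The named genes were completed by yvgK (log2 2.06, adjusted p = 0.0116) and bioFC (1.75, adjusted p = 0.0144) among those higher and by frlM (-2.61, adjusted p = 0.00309) among those lower in the mutant. For frlB, frlM, fldN and fldP the mutant signal was well above background on 1 of 2 slides. The count depended on single slides: it was 110 without exponential replicate 1, 814 without exponential replicate 2 and 27 with either 1 of the stationary slides left out, of which 46, 46 and 25 were among the 46 genes in the same direction. Without an exponential slide the exponential effect rests on 1 slide in 1 dye orientation, so a dye effect does not cancel there. With median centring in place of loess 2 genes rose and 10 fell. With the authors' log ratios, which cover 1739 genes on exponential replicate 1, limma called 1 gene, yxeD. This gene was chosen after its value was seen and is absent from the 46.

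Competence genes, for DNA uptake, were higher as a group. Of 36 measured members 31 had a positive ratio, 6 rose (comEA, comFA, comFB, comFC, nucA and nin) and 0 fell. Adjusted over the list alone, 19 were higher and 0 lower, and the list passed camera (limma, adjusted p = 6.5e-12; adjusted p = 0.605 with an estimated correlation). The median log2 ratio of the list was 0.86. Among its members comFA had a log2 ratio of 1.70 and the DNA-entry nuclease gene nucA one of 1.66. Of 16 genes of anaerobic respiration and fermentation, 4 rose (narG, narH, narJ and narK, the last at log2 1.67), 0 fell and 14 had a positive ratio. Adjusted over the list alone, 6 were higher and 1 lower (median 0.35, camera adjusted p = 0.000171; adjusted p = 0.605 with an estimated correlation). The median was 0.084 without exponential replicate 1 (camera adjusted p = 0.0414) and 0.64 without replicate 2. Of 54 genes of SigD-dependent motility and chemotaxis, 2 rose and 0 fell, with 5 higher adjusted over the list alone (camera adjusted p = 0.000929; adjusted p = 0.605 with an estimated correlation). Those that rose were flgM, for the inhibitor of SigD (log2 1.38, adjusted p = 0.0438), and yvyF (1.37, adjusted p = 0.0480). Both follow comFC on the chromosome, with 3 other list members behind them, a subset chosen after their values were seen. Of the 54 genes 5 were well above background in both channels of both slides, 4 of them in this run. Without the run, 0 of 49 genes passed limma's test (5 at an unadjusted p under 0.05, all higher; 8 passed without background correction) and the median was 0.24 (camera adjusted p = 0.0261; adjusted p = 0.605 with an estimated correlation).

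Lists of iron uptake, CodY-repressed uptake and amino acid synthesis were among those lower in the mutant. Of 26 Fur-controlled iron uptake genes, 4 fell and 0 rose, with 9 lower adjusted over the list alone (median log2 -0.62, camera adjusted p = 2.74e-07; adjusted p = 0.605 with an estimated correlation). They were dhbA (log2 -2.36), dhbB (-2.37) and dhbE (-2.42), for synthesis of the siderophore bacillibactin, and yfhC (-2.38, mutant signal well above background on 1 of 2 slides). Of 39 CodY-repressed nutrient uptake genes, 6 fell, all of the frl operon, and 12 were lower adjusted over the list alone (camera adjusted p = 6.34e-06; adjusted p = 0.605 with an estimated correlation). Among them frlD had a log2 ratio of -2.23 and frlO one of -2.41. The mutant signal of these 6 genes was well above background on 1 of 2 slides, and 4 of the 39 genes were well above background in both channels of both slides (median -0.13). Of 34 genes of arginine, histidine and tryptophan synthesis, 5 fell, all for arginine or carbamoyl phosphate, and 7 were lower adjusted over the list alone (median -0.54, camera adjusted p = 7.89e-06; adjusted p = 0.605 with an estimated correlation). In the branched-chain amino acid list, 1 of 11 genes, ilvC (-1.56, adjusted p = 0.0296), fell and 5 were lower adjusted over the list alone (camera adjusted p = 0.0102; adjusted p = 0.605 with an estimated correlation). In the methionine and cysteine list, 1 of 42 genes, the methionine synthase gene metE (-1.61, adjusted p = 0.0297), fell, 8 were lower adjusted over the list alone and the median was -0.077 (camera adjusted p = 0.0130; adjusted p = 0.605 with an estimated correlation).

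A further set of lists passed the camera test with no member past limma's threshold over all genes. Aminoacyl-tRNA synthetases had a median log2 ratio of -0.38 over 23 genes, with 1 higher and 8 lower at an unadjusted p under 0.05 and 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00151; adjusted p = 0.605 with an estimated correlation). The threonyl-tRNA synthetase genes thrS and thrZ had ratios of -1.28 and -1.18. This was also the list that passed fry (adjusted p = 0.0367). SigB-dependent stress genes, 8 of 54 well above background in both channels of both slides, were lower (median -0.23, camera adjusted p = 0.0195; adjusted p = 0.605 with an estimated correlation). So were genes of the prophage PBSX (median -0.36 over 32, camera adjusted p = 0.00222; adjusted p = 0.605 with an estimated correlation), of which 1 was well above background in both channels of both slides. The SigB and PBSX lists each had 0 genes past limma's threshold adjusted over the list alone. At an unadjusted p under 0.05, 11 SigB-dependent genes and 4 PBSX genes were lower and 3 SigB-dependent genes higher. Cell wall, teichoic acid and division genes were higher (median 0.19 over 58, camera adjusted p = 0.00154; adjusted p = 0.605 with an estimated correlation). Genes of the respiratory chain and ATP synthase were higher too (median 0.26 over 37, camera adjusted p = 0.0111; adjusted p = 0.605 with an estimated correlation). The cell wall and respiratory lists each had 0 genes past limma's threshold adjusted over the list alone, with 8 and 5 genes higher at an unadjusted p under 0.05. Of the 34 lists 21 did not pass camera. Without exponential replicate 1, whose mutant channel had the high background, the respiratory list had a median of -0.016, the cell wall list 0.10 and the PBSX list -0.18. Without exponential replicate 2 these medians were 0.45, 0.39 and -0.44. Each of these fits leaves 1 exponential slide in 1 dye orientation, so a dye effect does not cancel. Without replicate 1 the medians were 0.94 for competence, -0.57 for iron uptake and -0.39 for arginine, histidine and tryptophan synthesis. They were -0.38 for the methionine and cysteine list, -0.48 for the branched-chain list, -0.52 for the synthetases and -0.22 for the SigB list. With a dye term 16 of 35 competence, 5 of 52 SigD-dependent, 5 of 16 anaerobic and 1 of 37 respiratory genes rose. There 8 of 25 iron uptake, 9 of 39 CodY-repressed, 7 of 33 arginine, histidine and tryptophan, 8 of 38 methionine and cysteine, 2 of 11 branched-chain, 2 of 22 synthetase and 2 of 53 SigB-dependent genes fell. Without background correction the camera adjusted p was 0.422 for the SigB list (median -0.11), 0.346 for the respiratory list, 0.0614 for the cell wall list and 0.582 for the PBSX list. With median centring it was 0.451, 0.0922 and 0.116 for the respiratory, cell wall and PBSX lists. Without exponential replicate 2 the camera adjusted p was 0.318 for the synthetases, 0.293 for the SigB and SigD lists, 0.525 for the branched-chain list, 0.15 for the CodY list and 0.984 for the methionine and cysteine list.

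**Figure D2:**
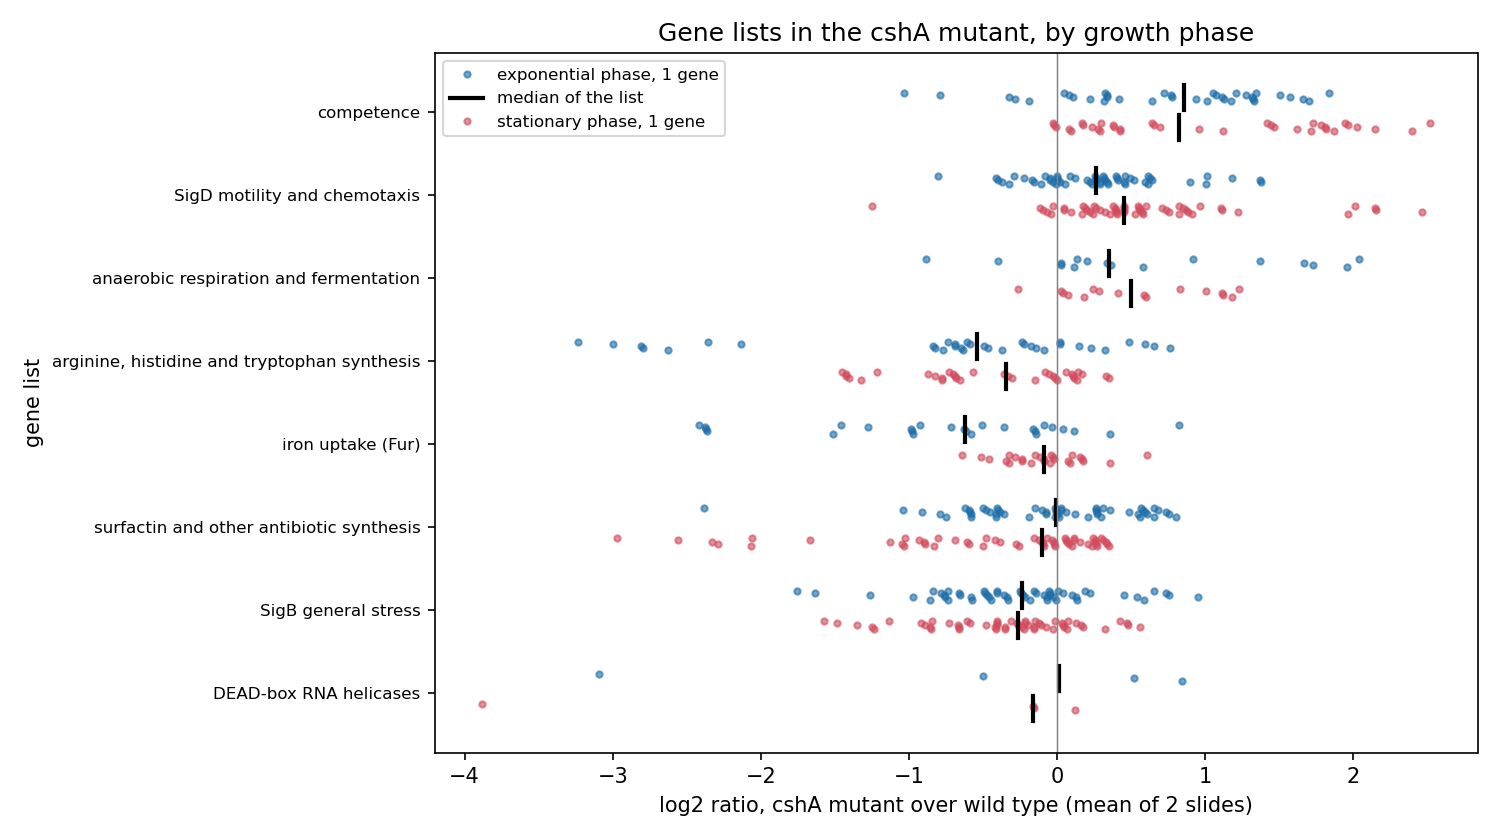
Mean log2 ratio of cshA mutant over wild type (2 slides per phase) for each measured gene of 8 gene lists, in exponential phase (blue) and stationary phase (red), with the list median as a black bar. The competence medians were 0.86 and 0.83, the iron uptake median was -0.62 in exponential phase, and the lowest dot of the DEAD-box list is cshA itself, at -3.09 and -3.88.

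Of the 22 other DEAD-box helicase and RNA degradation genes, 0 passed limma's test in exponential phase, with log2 ratios between -0.53 and 0.84 and a lowest adjusted p of 0.268 (1 gene, deaD, at an unadjusted p under 0.05). In stationary phase 0 passed limma's test, with ratios between -0.24 and 0.39 (0 at an unadjusted p under 0.05). The helicase genes cshB, deaD and yfmL had exponential log2 ratios of 0.52, 0.84 and -0.50, and rny, for the endoribonuclease RNase Y, had -0.33. In stationary phase these were 0.12, -0.17, -0.15 and -0.15.

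In early stationary phase the largest increases in the mutant lay in a run of neighbouring competence and flagellar genes. The competence gene comFA, for a DNA uptake ATPase, was 5.74-fold higher (log2 2.52, SE 0.26, n = 2, limma adjusted p = 0.00295), flgM 5.52-fold (2.46, SE 0.26, n = 2, adjusted p = 0.00295) and comFB 5.28-fold (2.40, SE 0.26). The genes yvyF, comFC, flgN, flgK and flgL followed with log2 ratios of 2.16, 2.15, 2.15, 2.01 and 1.96. Elsewhere on the chromosome comEA (2.03, SE 0.28) and nin, for the inhibitor of NucA (1.97, SE 0.28), rose. Besides cshA, the largest decreases were those of BSU01930 (9.35-fold, log2 -3.23, SE 0.26, n = 2, limma adjusted p = 0.00178) and of skfB, for production of the sporulation killing factor (7.84-fold, -2.97, SE 0.27, n = 2, adjusted p = 0.00243). The neighbouring genes skfA, skfF and BSU01940 had log2 ratios of -2.56, -2.33 and -2.36 and fell with it. The cytochrome P450 gene of pulcherriminic acid synthesis, cypX, and its neighbour pchC were 6.43- and 6.29-fold lower (-2.68, SE 0.30, and -2.65, SE 0.29), and yfmG and BSU07470 had ratios of -2.33 and -2.30.

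Of 4088 genes tested in stationary phase, 22 rose and 22 fell (limma, Benjamini-Hochberg), and 265 had an unadjusted p under 0.05. With either 1 of the stationary slides left out the count was 0 in limma (96 and 94 genes at an unadjusted p under 0.05, without replicates 1 and 2), and with either 1 of the exponential slides left out it was 191, of which 44 were among the 44. It was also 0 with median centring (192 at an unadjusted p under 0.05) and with the authors' log ratios (269). With scaling between slides 68 rose and 113 fell.

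Competence was the list with the most changed members in stationary phase. Of 36 genes, 15 rose and 0 fell, 33 had a positive ratio, and 18 were higher adjusted over the list alone (median log2 0.83, limma camera adjusted p = 7.26e-33; adjusted p = 0.508 with an estimated correlation). Of 54 SigD-dependent genes, 5 rose, 48 had a positive ratio and 12 were higher adjusted over the list alone (median 0.45, camera adjusted p = 3.9e-22; adjusted p = 0.508 with an estimated correlation). The 5 that rose are those downstream of comFC, and of the other 49 list members 43 had a positive ratio, with a median of 0.41, and 0 passed limma's test, with 14 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 2.39e-14; adjusted p = 0.508 with an estimated correlation). Of 16 genes of anaerobic respiration and fermentation, 15 had a positive ratio, 0 passed limma's test over all genes, 6 were higher at an unadjusted p under 0.05 and 6 adjusted over the list alone (median 0.50, camera adjusted p = 1.19e-07; adjusted p = 0.515 with an estimated correlation). Here narG stood at log2 1.23 and the regulator gene fnr at 1.18. Genes of the prophage PBSX had a median of 0.17 over 31 genes, with 0 past limma's threshold and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.00821; adjusted p = 0.508 with an estimated correlation). Without stationary replicate 2 this list did not pass (0.15, adjusted p = 0.231). With exponential replicate 1 left out, so that the spread came from the stationary slides alone, 6 of 16 anaerobic genes rose in limma's test and 15 of 53 SigD-dependent genes, 10 of them outside the run after comFC.

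Among the lists lower in stationary mutant cells, surfactin and other antibiotic synthesis had 7 of 55 genes that fell, namely skfA, skfB, skfE, skfF, skfG, skfH and the immunity gene sdpI. Adjusted over the list alone 12 were lower, and the median was -0.10 (camera adjusted p = 5.66e-08; adjusted p = 0.508 with an estimated correlation). The name of the list covers more than these members, which belong to the killing factor and toxin immunity systems. Of 15 pyrimidine synthesis genes, 14 had a negative ratio, 0 passed limma's test, over all genes or adjusted over the list alone, and 8 were lower at an unadjusted p under 0.05 (median -0.78, camera adjusted p = 1.11e-07; adjusted p = 0.508 with an estimated correlation). The lowest p values belonged to pyrK (log2 -1.04) and pyrAA (-1.16). Of 26 biofilm matrix genes 23 had a negative ratio, 0 passed limma's test over all genes, 7 were lower at an unadjusted p under 0.05 and 2 adjusted over the list alone (median -0.34, camera adjusted p = 3.23e-07; adjusted p = 0.508 with an estimated correlation). The amyloid fibre gene tasA had -1.39 (limma adjusted p = 0.0605) and the signal peptidase gene sipW -1.29. Of 54 SigB-dependent stress genes 1 fell and 6 were lower adjusted over the list alone (median -0.27, camera adjusted p = 1.12e-06; adjusted p = 0.508 with an estimated correlation). That gene was bmrU, at least 2.53-fold lower, with its mutant signal not well above background on either slide, while sigB itself had a log2 ratio of -1.24 (adjusted p = 0.0888).

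The list of arginine, histidine and tryptophan synthesis had a stationary median of -0.34 over 34 genes, with 0 past limma's threshold and 10 lower at an unadjusted p under 0.05 (camera adjusted p = 9.96e-06; adjusted p = 0.508 with an estimated correlation). The slides disagreed on it: argJ had -2.37 on stationary replicate 1 and -0.28 on replicate 2, argC -2.39 and -0.46. Without stationary replicate 1 its median was -0.14 (camera adjusted p = 0.337). The CodY-repressed list had a median of -0.31 over 39 genes, 1 of which, frlB (log2 -1.54, adjusted p = 0.0284), fell, and 2 were lower adjusted over the list alone (camera adjusted p = 6.07e-05; adjusted p = 0.508 with an estimated correlation). Ribosomal protein genes had a median of -0.29 over 51 genes, with 0 past limma's threshold and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00349; adjusted p = 0.694 with an estimated correlation). Without stationary replicate 2 the median was -0.033 (adjusted p = 0.976). Of the 34 lists 23 did not pass camera. With exponential replicate 1 left out, 16 of 55 antibiotic, 8 of 15 pyrimidine, 3 of 26 biofilm, 11 of 54 SigB-dependent, 8 of 33 arginine, histidine and tryptophan, 5 of 39 CodY-repressed and 1 of 50 ribosomal genes fell in limma's test. With a dye term 17 of 35 competence, 8 of 52 SigD-dependent and 1 of 16 anaerobic genes rose. There 8 of 55 antibiotic, 1 of 15 pyrimidine, 2 of 26 biofilm, 4 of 53 SigB-dependent, 1 of 33 arginine, histidine and tryptophan and 2 of 39 CodY-repressed genes fell. Without stationary replicate 2 the median was -0.44 for the pyrimidine list (camera adjusted p = 0.0130) and -0.27 for the antibiotic list (adjusted p = 3.25e-08).

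**Figure D3:**
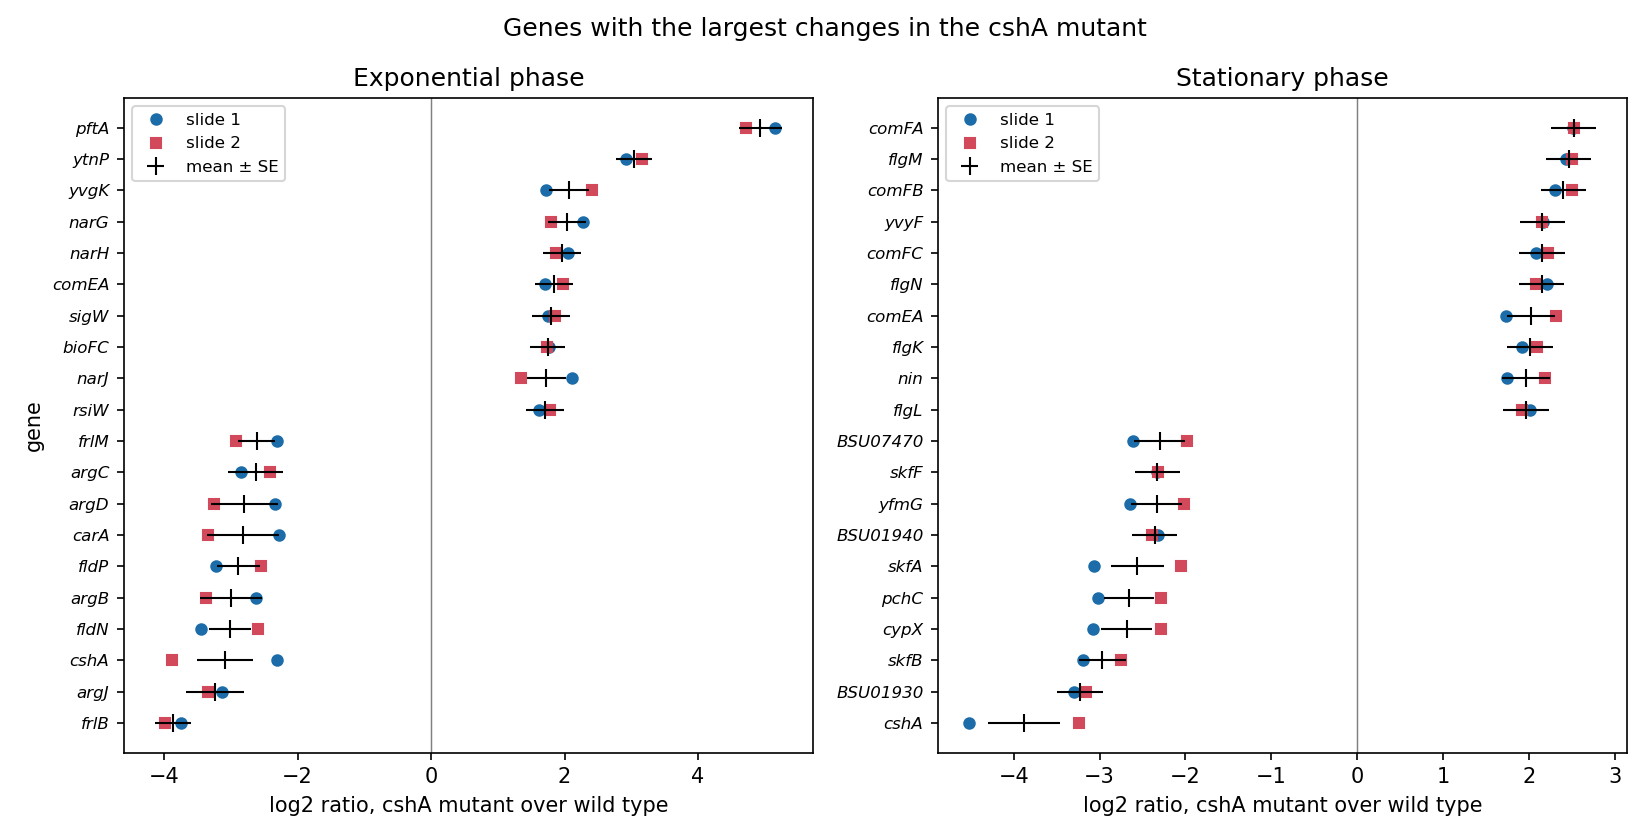
Log2 ratio of cshA mutant over wild type for the 10 genes with the highest and the 10 with the lowest ratio past the threshold in exponential phase (left) and stationary phase (right), with slide 1 as circles, slide 2 as squares and the mean with its standard error. In exponential phase the means run from -3.86 for frlB to 4.93 for pftA, and in stationary phase from -3.88 for cshA to 2.52 for comFA. The standard errors come from the fit of all 4 slides.

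Of the genes that rose, 10 did so in both phases (sigW, rsiW, nin, nucA, comEA, flgM, yvyF, comFA, comFB and comFC), 5 of them in the comF run. Of those that fell, 4 did so in both (cshA, frlB, sdpI and yvcI). The mean ratios of the phases correlated across genes with r of 0.417 and rho of 0.321. Stationary minus exponential effects, tested as a contrast in limma, passed for 2 of 4088 genes, both lower, with 157 at an unadjusted p under 0.05. The mutant's excess of pftA was 26.4-fold smaller in stationary phase (log2 -4.73, SE 0.46, adjusted p = 0.00793), where its ratio was 0.21, and that of ytnP 8.30-fold smaller (-3.05, SE 0.38, adjusted p = 0.0361). Short of the threshold were pchC (-2.83, adjusted p = 0.0729), BSU01930 (-2.50, adjusted p = 0.0729) and cypX (-2.36, adjusted p = 0.0972), lower in stationary phase. The genes fldN (2.79, adjusted p = 0.0854), fldP (2.69, adjusted p = 0.0922), frlB (2.32, adjusted p = 0.0854), dhbA (2.28, adjusted p = 0.0854) and dhbB (2.05, adjusted p = 0.0972) were higher there without passing. Without stationary replicate 1 the contrast passed for pftA alone (ytnP adjusted p = 0.455). Without stationary replicate 2 it passed for 0 genes in limma, with 51 at an unadjusted p under 0.05 (pftA -4.18, adjusted p = 0.147; ytnP adjusted p = 0.963). The count was 30 without exponential replicate 1, 413 without exponential replicate 2 and 0 with median centring (93 at an unadjusted p under 0.05) or the authors' log ratios (210).

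Entry into stationary phase was followed in each strain through its own channel. In the wild type, yjdB was 24.6-fold higher in stationary phase (log2 4.62, SE 0.30, n = 2 per phase, limma adjusted p = 3.42e-05), the molybdate transporter gene modA 13.9-fold (3.79, SE 0.23, adjusted p = 3.42e-05) and cypX 13.1-fold (3.71, SE 0.25). The genes yxeJ and walK were not well above background on either exponential slide and were at least 16.5- and 13.4-fold higher. The threonyl-tRNA synthetase gene thrZ was 18.6-fold lower (log2 -4.22, SE 0.23, n = 2 per phase, limma adjusted p = 3.42e-05), and dhbB (-3.74), fldP (-3.72), fldN (-3.65) and dhbE (-3.57) fell alongside it. Of 4088 genes tested, 147 rose and 240 fell in the wild type (limma, Benjamini-Hochberg), and 1049 had an unadjusted p under 0.05.

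Iron uptake, motility and amino acid synthesis lists had members that fell in stationary wild-type cells. Those given here as examples were chosen after their values were seen. Of 26 iron uptake genes, 15 fell and 0 rose, with the siderophore uptake genes feuA at log2 -1.95 and fhuC at -1.40. Of 54 SigD-dependent genes 21 fell, the flagellin gene hag among them (-2.27, limma adjusted p = 0.000674). Of 41 methionine and cysteine genes 15 fell, metE among them (-2.98), and of 34 arginine, histidine and tryptophan genes 12 fell, argJ among them (-3.39). Among 16 genes of anaerobic respiration and fermentation 6 rose and 2 fell, with narG at 1.89. Among 54 SigB-dependent genes 7 rose and 1 fell, with sigB at 0.97, and among 37 respiratory genes 6 rose and 1 fell, with the cytochrome oxidase gene ctaC at 2.10. All 6 named skf genes rose, by log2 1.85 to 2.73, while 3 of 36 competence genes fell. The wild-type count was 798 without exponential replicate 2, 251 without stationary replicate 1 and 210 without stationary replicate 2. Phase and slide cannot be told apart in this comparison.

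In the mutant, pftA was 39.9-fold lower in stationary than in exponential phase (log2 -5.32, SE 0.39, n = 2 per phase, limma adjusted p = 7.55e-06). The transcripts of thrZ (-3.89, 14.8-fold), ytnP (-3.30), cotNW (-2.75) and mtnA, of methionine salvage (-2.61), were lower too, thrZ with signal well above background on 1 of 2 stationary slides. Those of modA (4.09, 17.0-fold, adjusted p = 8.54e-05), modB (3.73) and yjdB (3.24) were higher, each with signal well above background on 1 of 2 exponential slides. The genes walK and yxeJ, not well above background on either, were at least 11.2- and 5.89-fold higher. In all, 13 genes rose and 10 fell (limma, Benjamini-Hochberg), and 548 had an unadjusted p under 0.05. Among lists, 2 of 23 aminoacyl-tRNA synthetase genes fell (thrS and thrZ) and 2 of 41 methionine and cysteine genes (mtnA and mtnK), whereas of 26 iron uptake genes 0 passed limma's test, with 8 lower and 1 higher at an unadjusted p under 0.05 and a median of -0.75. With median centring of channels 27 rose and 42 fell. The count was 79 without exponential replicate 1, 629 without exponential replicate 2, and 10 and 8 without stationary replicates 1 and 2. The smaller number of calls than in the wild type is not a tested difference between the strains.

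Counted without a test, 30 genes were at least 2-fold higher and 42 at least 2-fold lower in the mutant on both exponential slides, and 3 were at least 2-fold changed in opposite directions. On both stationary slides these counts were 30, 41 and 0. With median centring, 16 were higher, 62 lower and 26 opposite in exponential phase. With the authors' log ratios 17 and 57 genes were opposite in exponential and stationary phase. These counts are not comparable, because the authors' table holds 1739 genes on exponential replicate 1 against 4045 and 4043 on the stationary slides.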

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

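Of the tests weighed here, those of a gene-specific dye effect, of the competence genes and of the pftA probe were chosen after the results had been seen.

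The effect of the mutation differed between the phases for pftA by -4.73 and for ytnP by -3.05 on the log2 scale, the only genes of 4088 past limma's contrast of the phases. A defect of single spots is argued against: the paired spots of these genes differed by at most 0.417 on the log2 scale on the exponential slides, against ratios of at least 2.92. A probe that does not measure the pftA transcript stays open, because the smaller of the exponential log2 ratios of the neighbouring partner gene pftB was -0.048 while pftA stood at 4.93. A change in the mutant strain's own RNA, such as a part of the operon read or kept alone, may also give this pattern, and these slides hold no test of it. In the wild type pftA and ytnP changed between the phases by -0.59 and -0.25, short of limma's threshold.

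Lists lower in the mutant in exponential phase include some with members that fall when the wild type enters stationary phase. Examples are iron uptake (15 of 26 genes) and arginine, histidine and tryptophan synthesis (12 of 34 genes). No list test was run on the wild-type change. Mutant cultures further towards stationary phase at harvest may give part of this, since the mutant effect on each exponential slide and the wild-type change computed without that slide correlated across genes with r of 0.105 and 0.213, a mean of 0.159. The stationary slides gave -0.0457 and 0.0458. The competence genes went the other way, with a median of 0.86 in the mutant comparison and -0.30 in the wild-type change, a product of -0.255. This does not decide on harvest stage for them, because a rise between the sampled phases would not be seen. Of these 36 genes 3 passed limma's threshold in the wild-type change. The SigD and SigB lists, set beside competence after their values were seen, also went the other way. The SigD medians were 0.26 in the exponential mutant comparison and -0.77 in the wild-type change, where 21 of 54 genes fell. The SigB list was lower in the mutant and had 0.37 in the wild-type change (7 of 54 rose, 1 fell). Levels between the sampled phases are not seen for these lists either. The other lists that passed camera in exponential phase had medians of the same sign in both comparisons. A direct effect of the mutation on the transcripts of these lists stays open and was not tested apart from growth.

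The exponential slides correlated weakly over all genes. High Cy5 background on exponential replicate 1 may give part of this. Over the 876 genes well above background, the exponential r of 0.742 exceeded the stationary r of 0.653 over the same genes by 0.0890. The check does not single out background, because the stationary r was also higher over these genes than over all genes (0.397). The stationary slides, without such a background, had a rho of 0.118 over all genes, against 0.147 for the exponential slides. A gene-specific dye effect stays open: slides of the same dye orientation correlated more across phases than those of opposite orientation (difference of mean r 0.25). Across phases, rho over all genes was 0.411 and 0.432 for the pairs of the same orientation. For the pairs of opposite orientation it was -0.057 and 0.136. Within a phase it was 0.147 (exponential) and 0.118 (stationary). By rho, slides sharing an orientation thus agreed more than slides sharing a phase. Over genes well above background in both channels of both slides of a pair, Pearson r was 0.742 and 0.533 within a phase. Across phases it was 0.649 and 0.471 for the same orientation and 0.323 and 0.433 for opposite orientation. By rho over such genes, pairs of the same orientation had 0.644 and 0.435, against 0.601 and 0.257 within a phase. The order over these genes thus depended on the measure. Orientation coincides with replicate number in both phases. The biological difference between pools of cultures was not tested.

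Lists whose effects of the mutation differed between stationary and exponential phase by camera's test of the contrast are given next. Each value is the median, over the list's genes, of the stationary minus exponential log2 effect. It is not the difference between the list medians of the phases. For competence, the list median was not higher in stationary than in exponential phase. Higher in stationary phase were iron uptake, by 0.63 (adjusted p = 7.61e-08), the prophage PBSX, by 0.50 (8.19e-07), SigD-dependent motility, by 0.39 (3.28e-05), and competence, by 0.36 (0.00278). So were, by smaller medians, purine synthesis at 0.20 (0.0184), the aminoacyl-tRNA synthetases at 0.28 (0.0417) and CodY-repressed uptake at 0.078 (0.0116), the last with a direction that other settings turned. Lower in stationary phase were -0.90 for pyrimidine synthesis (1.62e-07), -0.31 for surfactin and other antibiotic synthesis (8.19e-07), and -0.13 for cell wall genes (0.00342). Also lower were -0.30 for the respiratory chain (0.00604), -0.26 for ribosomal proteins (0.0184) and -0.37 for fatty acid and phospholipid synthesis (0.0363). Without background correction, with median centring and without each slide in turn, the CodY contrast ran from -0.22 to 0.34, with -0.0031 under median centring. Over these settings the others ran from 0.55 to 0.83 for iron uptake, 0.052 to 0.67 for PBSX, 0.034 to 0.55 for SigD, 0.083 to 0.61 for competence, 0.24 to 0.39 for purine synthesis and 0.25 to 0.45 for the synthetases. Those lower in stationary phase ran from -1.13 to -0.64 for pyrimidine synthesis, -0.53 to -0.059 for antibiotic synthesis, -0.36 to -0.00077 for cell wall genes, -0.44 to -0.086 for the respiratory chain, -0.52 to -0.011 for ribosomal proteins and -0.35 to -0.15 for fatty acid synthesis. The antibiotic and cell wall contrasts were weakest without exponential replicate 1, and those of SigD, competence and PBSX without background correction. None of the 13 passed with an estimated correlation (adjusted p = 0.735 for ribosomal proteins and 0.683 for the others). In each list, 0 genes passed limma's contrast. Genes higher and lower at an unadjusted p under 0.05 were 7 and 0 for iron uptake and 3 and 0 for PBSX. They were 6 and 1 for SigD, 8 and 0 for CodY and 1 and 0 for purine synthesis. Pyrimidine synthesis had 0 and 6, antibiotic synthesis 0 and 7, and cell wall genes 0 and 3. The respiratory and ribosomal lists had 0 and 1. Competence (1 and 2), synthetases (0 and 1) and fatty acid synthesis (1 and 0) leaned against their direction. Signal appeared in spots that no comparison used: 11 of the 61 IDs without a locus tag were well above background in both channels of all 4 slides, and what they measure is not given in the sources used here. Of these 11, 1 had a higher net intensity in the mutant channel on every slide, through the swap of dyes, by log2 4.97 and 8.02 on exponential replicates 1 and 2 and 4.21 and 6.45 on stationary replicates 1 and 2, without normalization. The ratios of the other 10 did not keep a sign across the slides. All but 1 of them were lower in the mutant where it was labelled with Cy5 and higher where it was labelled with Cy3. Without normalization the sign thus followed the dye, and it cannot show whether these 10 differ between the strains.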

How the results depend on the processing

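The alternative restricted to genes well above background was chosen after the data had been seen. Counts of genes past limma's threshold are given as exponential (46), stationary (44) and difference between phases (2). They were 390, 177 and 61 without background correction, 17, 22 and 2 with plain subtraction (the last walK and yxeD, chosen after their values were seen), 12, 0 and 0 with median centring. They were 322, 172 and 31 with loess within grids, 84, 181 and 33 with scaling between slides, 81, 67 and 14 without dim genes, 148, 80 and 16 with a dye term. They were 174, 90 and 16 with replicate spots kept, 213, 130 and 28 with an intensity trend and robust prior. With other values they were 1, 0 and 0 with the authors' log ratios and 198, 58 and 31 over genes well above background. On the slides of the phase alone they were 27 and 191. Higher and lower calls split 2 to 10 with median centring in exponential phase and 68 to 113 with scaling between slides in stationary phase, against 21 to 25 and 22 to 22. The counts of 0 stand beside 192, 93, 269 and 210 genes at an unadjusted p under 0.05 (stationary and difference with median centring, then with the authors' log ratios). Leaving out each slide gave 27 to 814, 0 to 191 and 0 to 413. Without an exponential slide the spread comes from the stationary pair alone, and without a stationary slide from the exponential pair, so 191 and 27 recur. The 46 and 44 genes kept their call and direction in full with loess within grids, scaling, the filter on dim genes and the dye term. Stationary against exponential phase in the wild type (387) gave 213 genes with a separate-channel model and 210 to 798 without a slide. In the mutant (23) it gave 253 without background correction, 69 with median centring (27 higher, 42 lower), 92 without dim genes, 109 with a separate-channel model and 8 to 629 without a slide. At least 2-fold on both slides were 279 and 197 genes at a minimum of 1.5 and 31 and 26 at 3 (exponential, stationary), against 72 and 71. In stationary phase they were 44 without background correction and 112 with the authors' log ratios. With median centring, 16 were higher and 62 lower in exponential phase. Lists past the threshold (13 exponential, 11 stationary) numbered 0 and 0 with an estimated correlation (1 and 2 at an unadjusted p under 0.05) and 1 and 0 with fry (8 stationary lists at an unadjusted p under 0.05). Without a slide they numbered 7 to 13 and 10 to 12. The exponential ratio of cshA was -4.44 in the authors' values after conversion from natural log to log2, against -3.09 in the main fit. The slides' r was 0.566 and 0.453 without background correction, 0.0325 and 0.366 with median centring and, in stationary phase, 0.0251 in the authors' values. Direction turned for PBSX in exponential phase without background correction (median 0.060, camera adjusted p = 0.582). By camera's direction it also turned for the methionine and cysteine list without exponential replicate 2 (median -0.095, adjusted p = 0.984; median -0.38 without replicate 1) and for stationary ribosomal proteins without stationary replicate 2 (median -0.033, adjusted p = 0.976; median -0.46 without replicate 1). Of 79 named results past the threshold, 20 stayed past it under every alternative run for them that keeps all slides. All 20 are changes between phases, for which the authors' log ratios, plain subtraction, the dye term and loess within grids were not run, so they cannot be ranked against the mutant results. The other 59 lost it under at least 1, and 0 turned direction. With the authors' log ratios 0 of the 46 and 0 of the 44 genes kept their call. Losing the threshold under an alternative therefore does not set 1 mutant result apart from another. Of 110 not past it, 61 passed under at least 1. Signal over background limits exponential replicate 1 most. Except where a spread is named, the cause was not tested. The labels pair no slides. Dye orientation coincides with replicate number, so the fit with a dye term is also blocked on that number.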

Other observations

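The genes set out here were chosen after their values were seen. Neighbouring genes did not always move together. The run from comFA to flgL, 8 adjoining genes of the reference order, had 5 members past limma's threshold in exponential phase and 8 in stationary phase, with log2 ratios from 1.96 to 2.52 in the latter. In the siderophore operon, dhbA, dhbB and dhbE stood at -2.36, -2.37 and -2.42 in exponential phase. There dhbC and dhbF, with mutant signal well above background on 1 of 2 slides, stood at -0.031 and 0.11. In the wild type's change between phases dhbC and dhbF also stood apart, at -0.039 and -0.40 against -3.23 to -3.74. In the biotin operon bioFC had 1.75 in exponential phase, and bioB, bioD, bioI, bioK and bioW lay between -0.014 and 0.22. The gene walK rose in the wild type's change between phases, at least 13.4-fold, between walR at -1.29 (limma adjusted p = 0.0231) and walH at -2.09 (adjusted p = 0.0124). Whether the probes named walK, dhbC and dhbF measure those genes was not tested.

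The stationary mutant comparison and the wild type's change between phases share the stationary wild-type channels, so the ratio on each stationary slide is also given beside the change computed without that slide. The 6 named skf genes ranged from -2.06 to -2.97 in the stationary mutant comparison and from -0.15 to -0.91 in the exponential comparison, and rose by log2 1.85 to 2.73 in the wild type. The pair cypX and pchC had 3.71 and 3.39 in the wild type's change, -2.68 and -2.65 in the stationary mutant comparison and -0.33 and 0.18 in the exponential comparison. The contrast of the phases did not pass limma's threshold for cypX (adjusted p = 0.0972), pchC (adjusted p = 0.0729) or any of the 6 skf genes. In exponential phase the mutant signal of skfA, skfB, skfG, skfH and cypX was well above background on 1 of 2 slides. On slides kept apart, the ratios of the skf genes ran from -3.19 to -1.99 beside changes from 1.57 to 2.81, and those of cypX and pchC from -3.08 to -2.29 beside changes from 3.09 to 3.85.

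In the extracytoplasmic sigma factor list of 38 measured genes, sigW and rsiW rose in both phases (log2 1.80 and 1.71, then 1.69 and 1.63) and the list as a whole did not pass camera in either phase. The toxin immunity gene sdpI had -2.39 in exponential phase and -1.67 in stationary phase, and yvcI -2.24 and -1.70.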
